A study of Caenorhabditis elegans with 3 samples.

How the data were processed

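Levels of RNA were measured on 3 arrays of 2 colours, each comparing fem-1(lf) with fem-3(gf) animals, 1 prep of each genotype per array, and all 3 samples form 1 group in which the array is the replicate. The deposited values are log2 ratios of the 2 channels. The base was found from the values, since 2 to the power of the value is a whole number of thousandths for all but 4 of the 64209 values in the deposited table (tolerance 0.01), whereas base 10 and base e gave 3.40% or less. How the authors scaled or centred the arrays before they deposited the log2 ratios, whether they subtracted background or removed dim spots, and which dye each channel carried are not given in the sources used here. The medians of the arrays of preps 1, 2 and 3 were -0.15, -0.07 and -0.07, and their SDs 1.35, 1.15 and 1.22. No dye swap is stated, so an effect of dye cannot be taken out. Spot intensities were not analysed here, so no loess normalization and no filter on dim spots was applied, and no value can be weighed by its signal over background. No more than 0.32% of the values were identical between any 2 arrays.

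Rows were named through the platform annotation and the RefSeq gene table of assembly WBcel235, which was used for names, chromosomes and the order of neighbouring genes, with no coordinates printed. Of the 21611 rows, 16450 had 1 gene, 247 several and 4914 none. Of the rows with 1 gene, 16360 matched the table by gene ID, 8 by accession and 82 not at all. These gave 14956 named genes, 1449 of them with more than 1 row. Rows of a gene were averaged per array, and rows with several genes or none were kept as unnamed features. Features measured on all 3 arrays were tested, 19731 in all, of which 14795 were named.

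The log2 ratios were fitted as deposited, with no further centring, in limma 3.58.1 under R 4.3.3 (lmFit with an intercept against 0 and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), so the mean over 3 arrays is the measured value and the SD is that between arrays. An adjusted p without another name is from this fit, and folds are 2 to the power of the size of the mean. By sign choices alone, 3 arrays cannot give a two-sided p under 0.25, so the calls rest on the variance shared across features. The fit was tested on simulated data of 19731 features, 100 of them changed at each of 2 sizes. With variances drawn from the fitted distribution it recovered 33% of the features changed by 1 on the log2 scale and 96% of those changed by 2, with 3 false among 132 calls. With the shrunken variance of each feature it recovered 89% and 100%, with 24 false among 213 calls (11.3%), a share above the threshold of 0.05. Both simulations changed far fewer features than were called in the data and held no shift of whole arrays. The shares recovered may therefore differ in the data.

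Before the data were examined, 20 gene lists were fixed: the msp family, spermatogenesis and sperm function, oocyte and eggshell genes, germ granule and stem cell regulators, meiosis, cell cycle, DNA replication, ribosomal proteins, proteasome, respiratory chain, histones, vitellogenins, muscle, intestine, cuticle, neurons, somatic gonad, male somatic tissue, heat shock and stress, and protein kinases and phosphatases by description. The last was not run, since the gene table used has no descriptions, so 19 were tested. Each was tested with limma camera against all other features with a preset correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation. No list passed with an estimated correlation. With 3 arrays that test has few residual degrees of freedom, so its lack of calls does not separate strong lists from weak ones. Members were also counted with p-values adjusted over the list alone. Lists of muscle, intestine, cuticle and neuron genes together are called the somatic lists. The genes named were fixed by a rule: the 10 largest on each side with the same sign on all 3 arrays and at most 2 per symbol family, the 2 largest members on each side of each list that passed the test, and the check genes and mutated genes. Names outside the rule were chosen after their values were seen: the listed members that did not pass, the oocyte examples chs-1, spn-4 and glp-1, genes whose rows disagree, the X-linked examples, and all genes named first among the closing observations. Chromosomes were compared with two-sided Fisher's exact tests of the genes called at 2-fold or more, 12 tests adjusted together.

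The alternatives tried were centring each array on its median or on the somatic lists, scaling the arrays to the same spread, features measured on at least 2 arrays, leaving out each array, a robust variance model, each row on its own, an adjusted p under 0.01, limma treat against 1.5-fold, a 2-fold ratio on each array with no test, limma fry, no fold minimum, and chromosomes without msp genes and histones. Figures were drawn with matplotlib 3.10.9.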

Results

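Transcript levels were compared between Caenorhabditis elegans that make oocytes and animals that make sperm. The fem-1(lf) animals carry a loss-of-function mutation in fem-1, which leaves XX animals with oocytes and without sperm. The fem-3(gf) animals carry a gain-of-function mutation in fem-3, which leaves XX animals with sperm and without oocytes. RNA of the 2 genotypes was hybridised together on 3 arrays, each with 1 prep of fem-1(lf) RNA and 1 prep of fem-3(gf) RNA, numbered prep 1 to prep 3. The labels do not say that the preps came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The deposited table held 21611 rows, of which 21381, 21425 and 21403 had a value on the arrays of preps 1, 2 and 3, and 21168 had a value on all 3. After rows of the same gene were averaged, 19731 features were tested, 14795 of them named genes. Across genes, which are not independent replicates, Pearson correlations between the arrays lay between 0.92 and 0.93 and Spearman correlations between 0.78 and 0.84. The median SD of a feature between the arrays was 0.22 on the log2 scale. The number of arrays limits the precision of every value.

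Sperm genes lay far on the fem-3(gf) side of the ratio and oocyte genes on the fem-1(lf) side. The major sperm protein gene msp-142 had a mean log2 ratio of -4.57 ± 0.27 (SD, n = 3), and gsp-3, a sperm protein phosphatase, had -5.76 ± 0.53. The ferlin gene fer-1 and spe-9, which encodes a sperm surface protein needed at fertilisation, had -3.25 ± 0.16 and -2.58 ± 0.25. On the other side, oma-1, an oocyte maturation factor, had 2.097 ± 0.25, the yolk receptor gene rme-2 had 2.46 ± 0.66, the Pumilio-type RNA regulator puf-5 had 2.98 ± 1.05 and the eggshell proteoglycan gene cpg-2 had 2.78 ± 0.72. These 8 genes had limma adjusted p-values between 1.559e-05 and 0.001996, and each had the same sign on all 3 arrays. The labels name no dye: that a positive value means a higher level in fem-1(lf) was called likely, because each description names fem-1(lf) first and the source names put it in channel 2, and the sperm and oocyte genes went with that reading. The mutated gene fem-3 was itself 3.39-fold higher in fem-1(lf), at 1.76 ± 0.38 (limma adjusted p = 0.00075), whereas fem-1 was at 0.04 ± 0.21 (adjusted p = 0.83). Neither mutation is stated to remove the probed sequence, so neither level checks the labels. The ratio of msp-3 was -5.80 on every array, because the deposited ratios were rounded to thousandths and small ratios then fall on few steps.

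**Figure D1:**
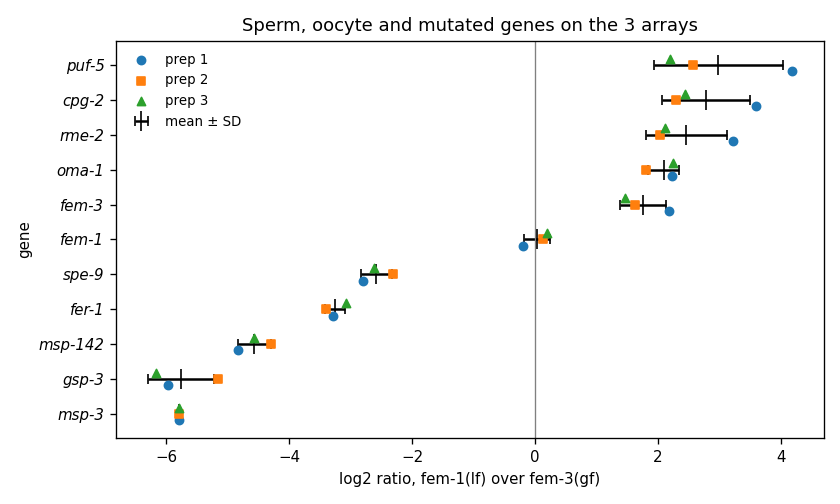
Log2 ratio of fem-1(lf) over fem-3(gf) on the horizontal axis for 11 genes, with a point for each of the 3 preps and a bar for the mean and SD over them. The sperm genes msp-3, gsp-3, msp-142, fer-1 and spe-9 lie between -5.80 and -2.58, the oocyte genes oma-1, rme-2, cpg-2 and puf-5 between 2.097 and 2.98, and fem-1 at 0.04.

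Genes higher in either genotype were numerous, and the largest differences were on the fem-3(gf) side. With limma, 4147 features (21.02% of 19731) were higher in fem-1(lf) and 4671 (23.7%) were higher in fem-3(gf). At least a 2-fold difference was seen for 1664 and 2005 of them, and at least a 4-fold difference for 201 and 1293. At least 16-fold was reached by 544 features higher in fem-3(gf), and 54 of these were at least 64-fold higher. The largest fold of a named gene was 12.99 on the fem-1(lf) side and 128 on the fem-3(gf) side. Among named genes alone, 3341 were higher in fem-1(lf) and 3537 in fem-3(gf), 1402 and 1527 of them by at least 2-fold. The balance of the sides depended on where 0 was set. As deposited, the median of all features was -0.10 and 47.03% of the calls were higher in fem-1(lf), against 56.5% after each array was centred on its median, 56.4% after scaling to the same spread and 70.9% after centring on the muscle, intestine, cuticle and neuron lists, which moved the median of all features to 0.18. Without prep 3, 2901 features were called higher in fem-1(lf) and 2739 in fem-3(gf).

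The genes with the largest fold on the fem-1(lf) side included factors of oocyte maturation and the eggshell. C50E3.12 on chromosome V led with 3.70 ± 0.57 (SD, n = 3, 12.99-fold, limma adjusted p = 0.000122), followed by EEED8.3 on chromosome II with 3.56 ± 0.71. The zinc finger gene oma-2 (ZC513.6, chromosome V), which acts with oma-1 in oocyte maturation, had 3.49 ± 0.58, and cpg-1 (C07G2.1, chromosome III), which encodes a chondroitin proteoglycan of the eggshell, had 3.22 ± 0.56. The C-type lectin gene clec-87 had 3.29 ± 0.70, the ribonuclease H gene rnh-1.3 had 3.10 ± 0.19, and gfat-2, which encodes an aminotransferase of the hexosamine pathway, had 3.06 ± 0.65. T02G6.5 had 3.28 ± 0.79, T22B7.7 on the X chromosome 3.20 ± 0.30 and pes-2.1 3.10 ± 1.42, the last with an array of prep 1 at 4.72 and the others at 2.09 and 2.48. Adjusted p-values of these 10 genes from limma lay between 3.08e-05 and 0.004984.

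The genes with the largest fold on the fem-3(gf) side were mostly of sperm-specific families. Genes of major sperm protein domains, msd-4 (C35D10.11, chromosome III) and msd-1 (F44D12.3, chromosome IV), had -6.997 ± 0.37 and -6.91 ± 0.50 (SD, n = 3), which are 128-fold and 120-fold higher in fem-3(gf). The major sperm protein genes msp-56 and msp-36, both on chromosome IV, had -6.88 ± 0.96 and -6.75 ± 0.09. The PDZ-domain sperm gene smz-1 had -6.63 ± 0.84 and the sperm-specific family member ssp-16 had -6.63 ± 0.35. T28H11.7 had -6.75 ± 0.09 with the same values as msp-36 on every array, msrp-2 -6.74 ± 0.82, C48E7.7 -6.66 ± 0.80 and nsph-3.1 -6.64 on each array. Adjusted p-values of these 10 genes from limma lay between 1.185e-05 and 5.995e-05. The smallest ratios on the arrays were 0.004, 0.006 and 0.007, so the rounding to thousandths makes values of this size coarse. Members of the msp, msd, smz and ssp families are alike in sequence, so a spot may report more than its own gene.

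All 30 measured genes of the msp family, whose products form the crawling skeleton of sperm and signal to oocytes, were higher in fem-3(gf), also when adjusted over the list alone, and 29 were after centring on the somatic lists. The member msp-38 stood apart, at -0.52 (limma adjusted p = 0.015), and was singled out after its value was seen. The median log2 ratio of the family was -6.19, a 73.1-fold difference (limma camera adjusted p = 4.106e-20, and adjusted p = 0.36 with an estimated correlation). In the wider list of spermatogenesis and sperm function genes, 41 of 43 were higher in fem-3(gf), with the same 41 counted when adjusted over the list alone, a median of -4.67 (camera adjusted p = 2.09e-21, and adjusted p = 0.36 with an estimated correlation) and smz-1 and ssp-16 at the head. The members that did not pass were spe-12 at 0.19 ± 0.29 and ssp-35 at 0.05 ± 0.12 (limma adjusted p = 0.34 and 0.74). The Argonaute gene alg-4 is among the 41, but its 2 rows gave -5.84 and -0.62.

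Oocyte, eggshell and maternal RNA genes were mostly higher in fem-1(lf). Of 42 measured, 38 rose in fem-1(lf), 1 fell and 3 did not pass, against 38, 3 and 1 when adjusted over the list alone. The median was 2.11 (4.32-fold, camera adjusted p = 2.308e-15, and adjusted p = 0.37 with an estimated correlation), and oma-2 and cpg-1 were the largest. The chitin synthase gene chs-1 was at 2.88 ± 0.13 (SD, n = 3), spn-4, a maternal RNA-binding regulator, at 2.94 ± 0.45, and the Notch receptor gene glp-1 at 1.90 ± 0.12, and these were picked as examples after their values were seen. The exception was perm-2, a gene of the eggshell permeability barrier, at -0.58 ± 0.25 (limma adjusted p = 0.021), which did not pass without prep 2 (-0.65), without prep 3 (-0.44) or after centring on the somatic lists (-0.30). The 3 that did not pass were perm-4 at -0.37, par-1 at -0.35 and par-2 at -0.05. The cold shock domain gene cey-2 rose, but its 2 rows gave 0.07 and 2.08.

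Genes of the mitotic and meiotic germline also lay on the fem-1(lf) side, while the pooled muscle, intestine, cuticle and neuron lists had a median of -0.31 over the arrays. Of the DNA replication genes, 26 of 29 were higher in fem-1(lf), or 28 of 29 adjusted over the list alone, with a median of 1.55 (2.93-fold, camera adjusted p = 5.451e-13, and adjusted p = 0.37 with an estimated correlation). The ribonucleotide reductase genes rnr-2 and rnr-1 were at 2.95 ± 0.70 and 2.66 ± 0.48. Of 29 genes of the meiotic chromosome axis, synapsis and recombination, 23 rose, or 25 adjusted over the list alone, with a median of 0.82 (camera adjusted p = 8.537e-10, and adjusted p = 0.36 with an estimated correlation). The crossover gene msh-4 was at 1.62 ± 0.47 and him-5, needed for crossovers on the X chromosome, at 1.58 ± 0.09. In the list of germ granule and germline stem cell regulators, 13 of 24 rose and 11 did not pass, against 17 and 7 adjusted over the list alone and 20 rising after centring on the somatic lists, with a median of 0.75 (camera adjusted p = 1.641e-06, and adjusted p = 0.37 with an estimated correlation). The translational repressor gene gld-1 was at 1.92 ± 0.55 and car-1, which encodes a germ granule protein, at 1.71 ± 0.30.

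Cell cycle and mitotic spindle genes also lay mostly on the fem-1(lf) side, but cyclins of the same type lay on opposite sides. Of 39 measured, 23 rose in fem-1(lf), 1 fell and 15 did not pass, against 24, 1 and 14 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 8.861e-08, and adjusted p = 0.37 with an estimated correlation). The B-type cyclin gene cyb-3 was at 2.99 ± 0.54 (SD, n = 3) and the cyclin-dependent kinase gene cdk-4 at 1.58 ± 0.34. The member that fell was another B-type cyclin gene, cyb-1, at -1.23 ± 0.15 (limma adjusted p = 0.00084).

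Among the lists of general cell machinery, proteasome genes and histones lay mostly on the fem-1(lf) side, with single members far on the other. Of 31 proteasome genes, 17 rose in fem-1(lf), 1 fell and 13 did not pass, against 19, 1 and 11 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 4.539e-06, and adjusted p = 0.37 with an estimated correlation). The lid subunit genes rpn-11 and rpn-6.1 were at 1.42 ± 0.24 and 1.29 ± 0.19 (SD, n = 3), whereas rpn-6.2, a paralog of the latter, was at -2.62 ± 0.45. Of 63 histone genes, 36 rose, 4 fell and 23 did not pass, against 38, 4 and 21 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 4.539e-06, and adjusted p = 0.37 with an estimated correlation). The H2A variant gene htz-1 was at 1.72 ± 0.26 and the linker histone gene hil-3 at 1.60 ± 0.67, against -4.95 ± 0.25 for the H3 variant gene his-70 and -1.57 ± 0.19 for the linker histone gene hil-8. Copies of the core histones are nearly identical, and the rows of his-66 and his-9 differed by 2.17 and 1.69, so single histone genes are uncertain. Spots of such copies may report the same RNA. The counts of histone genes and their camera p-value with the preset correlation may thus count 1 signal several times.

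Ribosomal protein, respiratory chain and stress genes had medians near 0 on the deposited scale. Of 61 ribosomal protein genes, 5 rose in fem-1(lf), 2 fell and 54 did not pass, and adjusted over the list alone 1 fell and 60 did not pass. Their median was 0.15 (camera adjusted p = 0.016, and adjusted p = 0.37 with an estimated correlation), or 0.095 without prep 1. After median centring 10 rose and 1 fell, after scaling 12 and 1, and after centring on the somatic lists 23 and 1, with a median of 0.43. The gene rpl-23 was at 0.74 ± 0.45 (0.50 without prep 2 and 0.77 without prep 3, no longer passing) and rps-24 at 0.57 ± 0.25 (0.45 and 0.57 likewise). On the other side rpl-42 was at -1.54 ± 0.17, with 2 rows that gave -2.46 and -0.61, and rpl-23A.1 at -0.40 ± 0.06, which did not pass without prep 1 (-0.37), prep 2 (-0.40) or prep 3 (-0.43), nor after centring on the median (-0.30) or the somatic lists (-0.11).

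Of 35 genes of the respiratory chain and ATP synthase, 5 rose, 3 fell and 27 did not pass, against 3, 2 and 30 adjusted over the list alone. The median was -0.01 and the mean -0.10, while the direction of camera was up (adjusted p = 0.45), and the median became 0.08 after centring on the array median and 0.27 after centring on the somatic lists, where 11 rose and 1 fell. It was also above 0 without prep 2 (0.03) and without prep 3 (0.07). Assembly factor genes of cytochrome c oxidase, cox-15 and cox-17, were at 1.02 ± 0.15 and 0.70 ± 0.12 (SD, n = 3), and a cytochrome c gene, cyc-2.2, was 51.6-fold higher in fem-3(gf) at -5.69 ± 0.79. The subunit gene cox-4 was at -0.55 ± 0.14, and did not pass without prep 3 (-0.55) or after centring on the somatic lists (-0.27). Of 26 heat shock and stress genes, 6 rose, 6 fell and 14 did not pass, against 7, 8 and 11 adjusted over the list alone. Their median was -0.12 and their mean -0.04, with camera up (adjusted p = 0.83) and a median of 0.16 after centring on the somatic lists, where 10 rose and 4 fell. The glutathione transferase genes gst-1 and gst-4 were at 1.26 ± 0.10 and 1.19 ± 0.83, the latter not passing without prep 2 (1.03) or prep 3 (0.87). The chaperone gene hsp-4 was at -1.13 ± 0.06 and the glutathione peroxidase gene gpx-1 at -0.97 ± 0.16.

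The medians of the yolk and somatic lists were below 0 on the deposited scale, most of these lists did not pass camera, and the counts of members that fell depended on where 0 was set. The yolk protein genes, made in the intestine and taken up by oocytes, were not higher in the oocyte-making animals: of 3 measured, vit-2 was at -1.53 ± 0.16 (SD, n = 3) and vit-6 at -0.61 ± 0.24, both past the limma test, and vit-5 at -0.37 ± 0.34 was not, with the same counts adjusted over the list alone (list median -0.61, camera adjusted p = 0.085). The call of vit-6 was lost without prep 3 (-0.66) and after centring on the somatic lists (-0.33). Of 38 intestinal genes, 4 rose in fem-1(lf), 17 fell and 17 did not pass, with the same counts adjusted over the list alone (median -0.40, camera adjusted p = 0.079). The median was -0.24 without prep 3, and after centring on the somatic lists it was -0.12, with 6 that rose and 5 that fell. That centring sets the pooled median of the muscle, intestine, cuticle and neuron genes to 0. For these lists its outcome was thus largely fixed in advance. The cathepsin B-like gene cpr-5 at 2.07 ± 0.20 and the metallothionein gene mtl-1 at 1.19 ± 0.22 rose, and the aspartyl protease gene asp-1 at -2.74 ± 0.34 and the lysozyme gene lys-7 at -1.31 ± 0.42 fell.

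Of 35 muscle genes, 2 rose, 11 fell and 22 did not pass, with the same counts adjusted over the list alone (median -0.32, camera adjusted p = 0.061, and -0.35 with adjusted p = 0.032 without prep 3). The median was -0.19 without prep 1, and after centring on the somatic lists 3 rose and 4 fell. The integrin gene pat-3 was at 1.55 ± 0.32 (SD, n = 3) and unc-60, a cofilin gene, at 0.59 ± 0.29, not passing without prep 1 (0.48) or prep 2 (0.54). Troponin genes pat-10 and mup-2 were at -1.07 ± 0.11 and -1.04 ± 0.24. Of 41 neuronal genes, 3 rose, 18 fell and 20 did not pass, against 4, 19 and 18 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.040, and adjusted p = 0.43 with an estimated correlation). That call was lost with any prep left out, with medians from -0.38 to -0.33, and after each centring or scaling tried, where 4 rose and 9 fell (median centring), 4 and 11 (scaling) or 6 and 2 (somatic lists). The neuropeptide gene flp-8 and the proprotein convertase gene egl-3 were at -0.82 ± 0.33 and -0.77 ± 0.22. On the other side were rgef-1 at 0.65 ± 0.47 (0.50 without prep 1 and 0.52 without prep 3, no longer passing) and unc-18 at 0.44 ± 0.19 (0.33 without prep 2 and 0.46 without prep 3, likewise).

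Of 152 cuticle collagen and hypodermal genes, 3 rose, 29 fell and 120 did not pass, and adjusted over the list alone 14 fell and 138 did not pass. Their median was -0.27 (camera adjusted p = 0.012, and adjusted p = 0.71 with an estimated correlation), and -0.10 without prep 1, which did not pass. Centring on the somatic lists, of which these genes are part, evens out their median by construction, here to 0.01, which did not pass. After median centring 5 rose and 17 fell, and after centring on the somatic lists 12 and 4. The collagen genes col-53 and col-151 were at -3.68 ± 0.40 and -1.58 ± 0.09 (SD, n = 3). Those that rose were led by col-98 at 0.48 ± 0.31 and col-86 at 0.46 ± 0.28. Their calls were lost without prep 3 (0.40 for each) and without prep 2 (0.39 for col-98) or prep 1 (0.36 for col-86), and for each gene also with features on at least 2 arrays (adjusted p = 0.052) and with each row on its own (adjusted p = 0.0504 for col-98 and 0.0507 for col-86).

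Of 17 genes of the somatic gonad, spermatheca and uterus, 2 rose, 5 fell and 10 did not pass, with the same counts adjusted over the list alone (median -0.25, camera adjusted p = 0.29, and a median of 0.03 with 2 that rose and 1 that fell after centring on the somatic lists). The median was -0.12 without prep 3. The gap junction gene inx-14 at 1.31 ± 0.50 (SD, n = 3) and the EGF-like ligand gene lin-3 at 1.10 ± 0.33 rose. Both are members of the list as fixed, and whether their RNA came from somatic or germline cells was not tested. The genes mig-6, at -1.10 ± 0.15, and ceh-18, a homeobox gene of gonadal sheath cells at -0.71 ± 0.15, fell, the latter not passing after centring on the somatic lists (-0.42). Of 16 genes of male somatic tissue, 3 fell and 13 did not pass, or 2 and 14 adjusted over the list alone (median -0.33, camera adjusted p = 0.069), and after centring on the somatic lists 1 rose and 1 fell. The protease inhibitor gene swm-1, which keeps sperm from early activation in males, was at -1.29 ± 0.10, and the kinesin gene klp-6 was at -0.55 ± 0.15, not passing without prep 2 (-0.46), prep 3 (-0.59), with each row on its own (-0.62) or after centring on the somatic lists (-0.27). All lists but the respiratory chain and the stress genes had a median of the same sign on all 3 arrays.

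**Figure D2:**
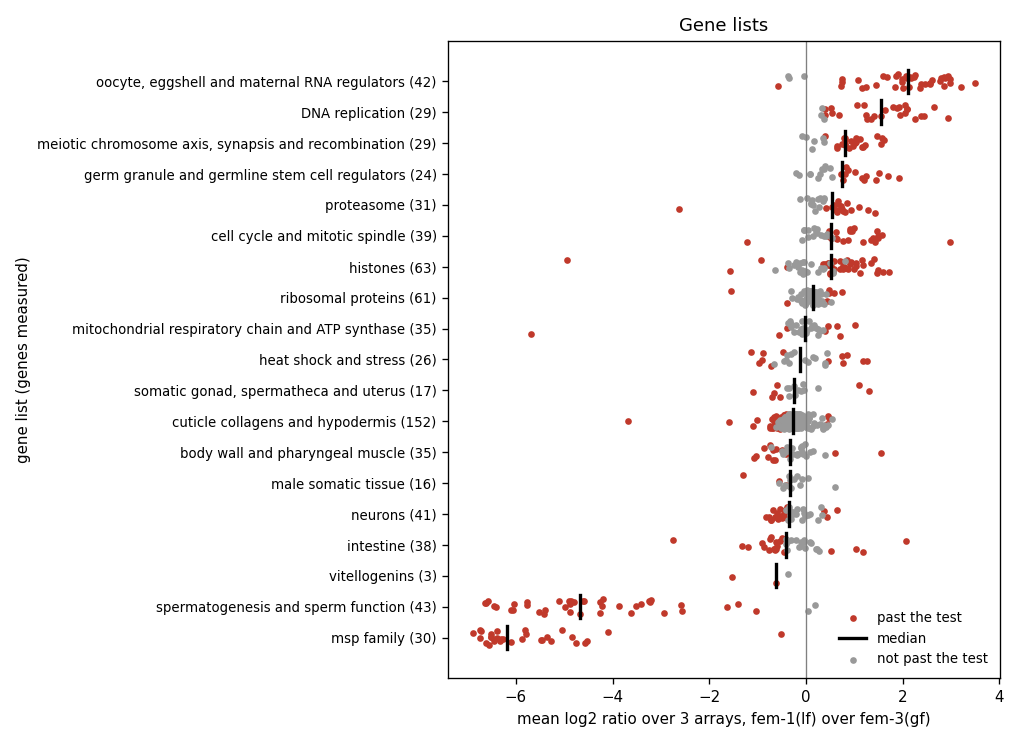
Mean log2 ratio of fem-1(lf) over fem-3(gf) over 3 arrays on the horizontal axis, with a point for each measured gene of 19 lists on the vertical axis, in red where it passed the limma test and in grey where it did not, and a black bar at the list median. Medians run from -6.19 for the msp family to 2.11 for oocyte genes, and after centring on the somatic lists those of the cuticle, somatic gonad, stress and respiratory chain lists change sign.

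Genes at least 2-fold higher in the sperm-making animals were scarce on the X chromosome and frequent on chromosomes IV and I. The Fisher tests of chromosomes on both sides take genes as independent. Called genes tended to lie side by side, so the p-values may be too small and the intervals too narrow. On the X chromosome, 54 of 2197 tested genes (2.46%, 95% Wilson interval 1.89 to 3.19) were at least 2-fold higher in fem-3(gf), against 11.7% of the genes elsewhere, an odds ratio of 0.19 with an interval of 0.14 to 0.25 (Fisher's exact test, two-sided, adjusted p = 1.453e-50 over 12 tests). Chromosome IV, which holds msp-56, msp-36 and msd-1, had 362 of 2213 genes on that side (16.36%, odds ratio 1.92, Fisher's exact adjusted p = 5.028e-21), and chromosome I had 305 of 1997 (15.3%, odds ratio 1.71, adjusted p = 3.102e-13). Chromosome V had 7.54% (odds ratio 0.64, adjusted p = 4.001e-11), chromosome II 11.7% (odds ratio 1.18, adjusted p = 0.019) and chromosome III 10.9% (odds ratio 1.07, adjusted p = 0.43). The X-linked genes furthest on the fem-3(gf) side were nspa-9 at -3.46 ± 0.30 (SD, n = 3) and F15G9.5 at -2.82 ± 0.59, the latter the mean of 2 rows that gave -5.25 and -0.38, and the yolk gene vit-2 and the troponin gene mup-2 were among the 54. Without the fold minimum the X odds ratio was 0.76 as deposited, 0.583 after median centring and 0.293 after centring on the somatic lists, and with the minimum it was 0.093 after the latter; these centrings of the X chromosome were chosen after the data were seen. Without the minimum, chromosome III, not called at 1.07, was called at 0.86 (adjusted p = 0.013), while the calls of chromosomes I (1.10), II (1.04) and V (0.92) were lost.

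Genes at least 2-fold higher in fem-1(lf) were spread more evenly. The X chromosome held 157 of 2197 (7.15%, against 9.91% elsewhere, odds ratio 0.70, Fisher's exact adjusted p = 4.255e-05), but 29 of the 172 genes at least 4-fold higher (16.9%, against 14.9% of tested genes, odds ratio 1.16, Fisher's exact p = 0.45). Chromosome V held 5.54% of its genes on that side (odds ratio 0.48, adjusted p = 2.517e-23). Chromosomes I and III stood above the others, with 14.2% and 13.5% (odds ratios 1.73 and 1.59, adjusted p = 4.742e-13 and 2.357e-09). Chromosomes II and IV had odds ratios of 1.14 and 1.04 (adjusted p = 0.073 and 0.64), and passed with 1.19 and 1.14 without the fold minimum. Copies of the msp genes and histones lie in clusters, and without these families the call of chromosome II on the fem-3(gf) side was lost, at an odds ratio of 1.15.

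**Figure D3:**
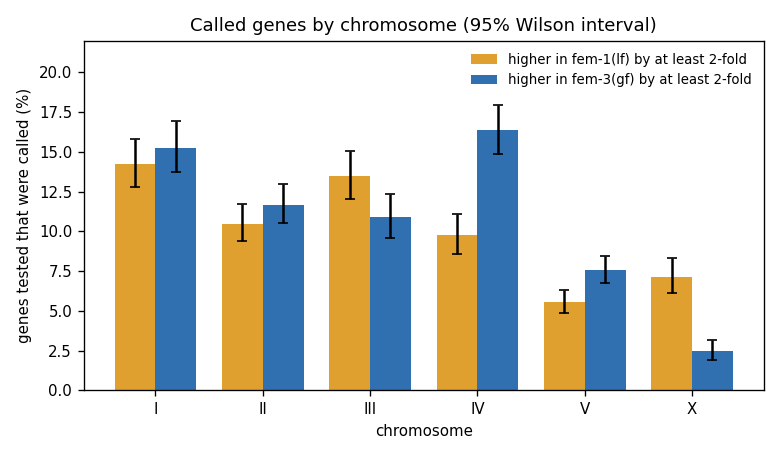
Percent of the tested genes of each chromosome that were at least 2-fold higher in fem-1(lf) (orange) or fem-3(gf) (blue) with a limma adjusted p under 0.05, with 95% Wilson intervals that cover counting error only. The blue bar of the X chromosome stands at 2.46%, against 7.54% to 16.36% on the other chromosomes.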

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

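The tests of the X chromosome with arrays centred on the somatic lists, or with no fold minimum and either centring, were chosen after the data were seen. Of the 8818 features called, 7762 stayed called after median centring, 6561 after centring on the somatic lists, 7897 after scaling and 7406, 6073 and 5555 without preps 1, 2 and 3, and 0 turned direction. Counts higher in fem-1(lf) and fem-3(gf) were 2699 and 2544 at an adjusted p under 0.01 and 1431 and 1814 with limma treat against 1.5-fold, where fewer features pass by construction. Centring on the somatic lists, which moves every feature up, gave 2435 higher in fem-3(gf) and 2803 at least 2-fold higher in fem-1(lf). A ratio of 2-fold on each array, with no test, gave 1026 higher in fem-1(lf). Without each prep in turn, counts ran from 2901 to 4028 higher in fem-1(lf) and from 2739 to 4057 higher in fem-3(gf), with fewer arrays in the fit.

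With an estimated correlation the calls were lost of the lists with medians of -6.19 (msp), -4.67 (sperm), 2.11 (oocyte), 0.75 (germ granule), 0.82 (meiosis), 0.52 (cell cycle), 1.55 (replication), 0.15 (ribosomal), 0.54 (proteasome), 0.52 (histones), -0.27 (cuticle) and -0.35 (neurons), with adjusted p-values from 0.36 to 0.71. With limma fry, which asks whether a set lies on balance on a side of 0 and not whether it differs from other genes, the calls of the vitellogenins (-0.61, adjusted p = 0.011) and male somatic genes (-0.33, adjusted p = 0.020) were gained and that of the cuticle (-0.27, adjusted p = 0.19) was lost. The neuron list lost its call with the median at -0.25 after median centring and after scaling (adjusted p = 0.0505 and 0.053), at -0.063 after centring on the somatic lists and without any prep (-0.38 to -0.33). The cuticle list lost it at 0.014 after centring on the somatic lists and without prep 1 (range without a prep -0.38 to -0.10), and muscle passed without prep 3 (range -0.38 to -0.19). Camera with an estimated correlation has few residual degrees of freedom with 3 arrays and could hardly pass any list. Its adjusted p was 0.364 for the msp family, with all 30 members called, and 0.370 for ribosomal proteins, with 54 of 61 not called. Those lost calls do not tell strong lists from weak ones. Centring on the somatic lists moves the neuron and cuticle medians near 0 by construction. The causes of the other changes were not tested.

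With no fold minimum, odds ratios higher in fem-1(lf) passed for chromosomes II (1.19) and IV (1.14), those higher in fem-3(gf) lost the call for I (1.10), II (1.04) and V (0.92), and III, not called at 1.07, was called in the other direction at 0.86. Chromosome II also lost it without msp genes and histones (1.15). The cause was not tested. Over all alternatives, named genes gave the same call in 718 cases, lost it in 38 and reversed in 0, and chromosomes gave the same call in 71, lost it in 4, gained it in 2 and, for chromosome III, gained 1 in the other direction. Centring on the somatic lists, added later, gave an X odds ratio on the fem-3(gf) side of 0.093, and with no fold minimum 0.293, or 0.583 after median centring. Features on at least 2 arrays were not run for lists, since camera takes no missing values. Each array already sets 1 prep of each genotype against the other, so the ratios form 1 group. The fit of these ratios against 0 is thus itself paired by array, and no further pairing was possible. Signal over background limits which small ratios can be trusted, and intensities were not analysed here.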

Other observations

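Gene families by symbol, the paralogs contrasted and the genes named with them were chosen after the data were seen. Tests of the 3 patterns weighed and of the signs were set before their results were seen. Not set then were the X chromosome with other centring, its breakdown by fold and the share of neighbours on the fem-1(lf) side. Of 272 families with at least 6 tested members, 15 held more genes at least 2-fold higher in fem-3(gf) than other background genes did, and 9 more in fem-1(lf). These were two-sided Fisher's exact tests, adjusted over 544 tests, and family members are not independent. The background held 9046 genes, fewer than the 14795 named genes tested. In the test of nspd, 6.47% of its other genes were called on the fem-3(gf) side, against 10.32% of all named genes. Families on that side therefore stood out more than they would against all named genes, and the number of 15 depends on this background. The tau tubulin kinase family ttbk had 8 of 9 on the fem-3(gf) side (median -3.81, adjusted p = 2.509e-07), with ttbk-2.1 at -5.97 ± 0.28 (SD, n = 3), but the 2 rows of ttbk-2.2, counted among the 8, gave -5.90 and -0.28. All 8 tested genes of nspd, a family of nematode-specific peptides, lay there (median -4.74), with nspd-6 at -6.15 ± 0.32, but the 2 rows of nspd-7 gave -6.31 and -0.63. Of the transthyretin-related family ttr, 21 of 44 did (median -0.89, adjusted p = 8.753e-12), or 11 after centring on the somatic lists. In that family ttr-9 was at -4.30 ± 0.15, whereas ttr-58 was at 2.21 ± 0.30. Of the ABC transporter families, abt had 5 of 6 genes there and wht 5 of 7 (medians -1.57 and -2.46), with abt-1 at -4.31 ± 0.25 and wht-5 at -4.10 ± 0.31, but wht-2 was at 1.297 ± 0.10, and pgp and haf had 0 of 14 and 0 of 6 genes there, with an adjusted limma p or with an unadjusted p under 0.05 (medians -0.33 and 0.05, adjusted p = 1 for each family). Acyl-CoA synthetase genes had 8 of 22 members on that side, with acs-10 at -5.44 ± 0.29, and neprilysin-like peptidase genes had 10 of 23, with nep-8 at -4.60 ± 0.57. On the fem-1(lf) side were 11 of 30 vps genes of vacuolar protein sorting (median 0.53), with vps-39 at 1.73 ± 0.35, and 4 of 6 sqv genes of glycosaminoglycan synthesis (median 1.26), with sqv-8 at 1.74 ± 0.04.

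In the sets of paralogs named here, picked after their values were seen, members lay on opposite sides, and other sets were not counted. Among type 1 phosphatase genes, gsp-3 was at -5.76 and gsp-2 at 1.16 ± 0.29 (SD, n = 3), and gsp-1 was at -0.15 ± 0.14. Among H3.3 genes, his-70 was at -4.95 and his-72 at 1.35 ± 0.30, with the limit given above for single histone genes. The CDC25 phosphatase gene cdc-25.4 was at -5.11 ± 0.78 and cdc-25.1 at 1.35 ± 0.31. Of 1044 tested chemoreceptor genes, 28 were called higher in fem-1(lf) and 102 in fem-3(gf), against 21.02% and 23.7% of all features. By at least 2-fold, 3 and 12 of the 1044 were called on these sides, against 8.43% and 10.16% of all features. The chemoreceptor gene srb-13 was at -6.17 ± 0.26. Of 1395 genes with more than 1 row measured on all arrays, 47 (3.37%) had rows at least 4-fold apart.

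Genes at least 2-fold higher in fem-3(gf) were scarce on the X chromosome, and more so as the fold grew. X held 383 of 1998 genes called by limma under 2-fold (19.2%, against 14.9% of tested genes) and 50 of 450 between 2-fold and 4-fold. It held 4 of 593 between 4-fold and 16-fold and 0 of 477 above, also 0 at an unadjusted limma p under 0.05. For the last the odds ratio was 0. The upper end of its 95% Fisher interval, which takes genes as independent, was 0.0426. A row of the X-linked gene F15G9.5 was however at -5.25 and its other row at -0.38. Clustered copies that share sequence were argued against, since with 1 gene per family and per run of neighbouring called genes the odds ratio was 0.176 (Fisher's exact p = 6.738e-29). Without the fold minimum the odds ratio was 0.761, past the bound of 0.67 set for the minimum as an explanation. The calls then added, those under 2-fold, were more frequent on X (odds ratio 1.43, Fisher's exact p = 2.853e-08). The minimum could account for part of the value at 2-fold. It does not act on the genes above 4-fold, of which X held 4 of 593 and 0 of 477. With arrays centred on the somatic lists and no minimum the odds ratio was 0.293, so the value without a minimum depends on where 0 is set. Low transcription of the X chromosome in the sperm-making germline stays open as a hypothesis, untested here.

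The muscle, intestine, cuticle and neuron lists lay below 0, with pooled medians of -0.48, -0.24 and -0.12 on the arrays of preps 1, 2 and 3. If an offset of dim spots were the cause, chemoreceptor genes would lie as low; they lay 0.324, 0.164 and 0.0914 above the somatic lists, and the last is within the bound of 0.10. If the centring of the arrays were the cause, all features would; they lay 0.339, 0.177 and 0.0509 above. Each explanation stays open because of prep 3, and a difference between the genotypes in the share of somatic RNA may also account for it, untested here.

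Genes at least 2-fold higher in fem-3(gf) tended to lie side by side: for 409 of 1520 (26.9%) the next tested gene on the chromosome was such a gene, against a mean of 12.29% and a highest value of 14.3% in 1000 shuffles of gene order within chromosomes. Copies of the same symbol family were argued against as the whole cause, since the share was 26.3% without such neighbours, above the highest of 15.4% in those shuffles. Genes named only by their locus share no symbol, and 1462 of the 1520 genes stayed. The share could therefore change little, and it does not bear on copies among locus-named genes. Germline expression shared by neighbours, as in regions or operons, may account for it as a hypothesis, and copies with unlike symbols were not tested. On the fem-1(lf) side the share was 18.7%, against a highest of 13.02%.

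Of the 4 choices of sign for the 3 arrays, 1, the real choice itself, gave as many called features, with 8818 for the real signs and 0 for the highest other. Since the arrays ran the same way, turning the sign of 1 of them raises the spread of every gene that differs. The contrast therefore restates the agreement of the arrays and does not bear on chance. These choices are also too few for a share under 0.05.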
